A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

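Per the labels, cells were grown in YPD or dropout media, RNA was extracted with hot phenol and treated with DNase, and poly-A selected libraries were prepared. Per the submitters' processing notes, reads were trimmed with cutadapt (version not given in the sources used here) and quantified with Salmon 1.9 against sacCer3. Read layout, strand setting, trimming parameters and the index options are not given in the sources used here. The deposited values are the estimated counts and the TPM that the authors had from Salmon, 1 table per library over 6571 coding sequences. The counts are not whole numbers, since Salmon divides reads that fit several sequences, and they were rounded to whole numbers before the tests. The sequences are spliced coding sequences without untranslated regions or introns, so the unspliced share of a gene was not analysed here. Total assigned reads ran from 28.5 to 46.8 M per library.

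Genes were matched by systematic name to the R64 annotation. Of the 6571 sequences 5906 matched and 665 did not; in 5886 of the matched genes the coding length equalled that of the annotation. An intron was a gap of 20 bases or more between coding segments of a nuclear protein-coding gene, which gave 269 genes, 89 of them ribosomal protein genes and 10 with more than 1 intron. The 5′ splice site was the first 6 bases of the first intron. Overlapping and antisense neighbours cannot be separated without a known strand setting, and reads divided between near-identical copies leave each copy uncertain.

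Libraries were grouped by their labels into 7 groups of 3. The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined, unless said otherwise. Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter at its defaults, quasi-likelihood fits without a block, and Benjamini-Hochberg adjusted p below 0.05 as a call. Wildtype, humanized and triple mutant libraries at low density shared 1 fit. The high-density pair and the degron pair each had their own, and the interaction and the comparisons of density used a fit of the 4 wildtype and humanized groups. SE is the standard error of the log2 fold change. CPM in the target and marker paragraphs, and of STE2 and URA3 in the closing section, are reads divided by M assigned reads. CPM given in brackets with a fold change are TMM normalized within the fit of that comparison. Values drawn or called normalized CPM are TMM normalized over all 21 libraries. The same gene and group can therefore have different values on these scales. Genes whose groups did not overlap had every library of one group above every library of the other, which 3 against 3 libraries give by chance in 10% of genes.

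Of 37 gene lists fixed in advance 36 were used as sets, and 35 reached the minimum of 4 tested members in each comparison. They were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Over all 8 comparisons 123 of 280 list tests were called with the preset value and 3 with the estimated one. The list medians are over tested members. Differences by splice site and correlations with intron length or baseline expression used 100000 permutations of genes, so their p-values treat genes as independent and cannot fall below 1e-05. Intervals on medians came from 2000 bootstrap samples of genes.

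Genes named in the text were YHC1 and LUC7, then the 6 highest and 6 lowest called genes with non-overlapping groups and a mean of 10 CPM or more (4 and 4 in comparisons without a control), then members of called lists in order of p until 20 further genes, then fixed members of the intron and respiratory lists. The text leaves out part of the genes that met this rule, mainly further members of lists and genes of the comparisons without a control, and this was decided with their values in view. The result of 1 other gene is not reported here. Further members of the lists are named in the closing section where said.

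Alternatives were DESeq2 size factors in the same fit, TMM from genes outside the cytosolic ribosome, no filter or a mean of 10 CPM, DESeq2 1.42.0, limma-trend on log2(TPM + 1), all 7 groups in 1 fit, only the 2 compared groups, the replicate number as a block, and each library left out in turn. Chosen after the data had been seen were an offset per library from a spline with 4 degrees of freedom on coding length and GC content, leaving out both wildtype libraries numbered 2, the bootstrap intervals, the difference between ribosomal protein genes with and without introns, medians by single splice site, and the overlap of the triple mutant with the depletion. Correlations of deviations between libraries of the same number ran from −0.51 to 0.68 over the comparisons, and in no comparison were all 3 above 0.1. For density in wildtype 2 of 3 were (0.08 to 0.68), and in the depletion 2 of 3 (−0.13 to 0.17), so a pairing there is not excluded.

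Before the tests the methods were tried on counts drawn from negative binomial distributions at the depths, means and spreads of the real libraries, with 200 genes changed by known folds. Each gene was drawn on its own, without the real trends of libraries with coding length and GC content. The shares found therefore hold for libraries without such trends and may differ in the real data. At 1.25-fold, 1.5-fold, 2-fold and 4-fold the share found was 58, 84, 100 and 100% in humanized cells at low density, 48, 92, 96 and 100% in the triple mutant, 50, 88, 98 and 100% between those mutants, 18, 64, 86 and 98% at high density, 54, 82, 100 and 100% in the depletion, and 8, 52, 72 and 100% in the interaction. For density it was 24, 78, 92 and 100% in wildtype and 34, 78, 90 and 98% in humanized cells. Groupings were also exchanged: all 10 splits of 3 against 3 libraries, and 100 of 200 drawn for the interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.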

Results

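Polyadenylated RNA of Saccharomyces cerevisiae was counted over the coding sequences of the R64 (sacCer3) build in 21 libraries, 3 from each of 7 groups. A strain carrying a humanized U1-C, the U1 snRNP protein encoded by YHC1, and its wildtype were sampled at low density (OD600 near 0.4) and, in an earlier experiment, at high density (near 5 for wildtype and near 8 for the humanized strain). A Luc7 triple mutant was labelled low density, and a strain with a degron on Luc7 was sampled without IAA and after 6 hours of beta-estradiol and IAA. Luc7 is a second U1 snRNP protein that acts at the 5′ splice site. Libraries held 29.1–30.4 M assigned reads in wildtype and 31.4–32.8 in humanized cells at low density, 36.3–46.3 in the triple mutant, 29.6–45.5 and 30.4–46.8 in wildtype and humanized cells at high density, and 31.7–39.3 and 28.5–34.2 in undepleted and depleted degron cells. The coding sequences were spliced ones, so unspliced RNA was not analysed here, and reads from exons of unspliced transcripts also counted toward an intron gene. The p-values below measure the spread between libraries, since the labels do not say that replicates were separate cultures.

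YHC1 had 31.5–36.7 reads per M assigned (CPM) in the 3 wildtype and 27.3–29.7 in the 3 humanized libraries at low density, 28.7–30.7 in the triple mutant, 34.9–39.7 and 28.1–35.1 in wildtype and humanized cells at high density, and 30.2–35.0 and 42.5–47.0 in undepleted and depleted degron cells. LUC7 in the same order had 35.5–40.3, 46.9–56.9, 33.2–39.9, 31.9–38.7, 38.1–47.0, 83.8–136 and 116–168 CPM. In humanized cells YHC1 (chromosome XII, 724721–725416) was lower at low density (log2 fold change −0.30 ± 0.07, mean ± SE, 3 libraries per group, adjusted p = 0.0279) and at high density (−0.35 ± 0.09, adjusted p = 0.0284). It was lower in the triple mutant too (−0.21 ± 0.07, adjusted p = 0.0197) and not called between the mutants (+0.09 ± 0.07, adjusted p = 0.345). A humanized coding sequence is counted only where it matches the yeast sequence, so these values do not measure its transcript in full. LUC7 (IV, 300214–300999) was higher in humanized cells at low density (+0.37 ± 0.09, adjusted p = 0.0389) and was not called at high density (+0.24 ± 0.11, adjusted p = 0.151) or in the triple mutant (−0.10 ± 0.09, adjusted p = 0.360). The low-density YHC1 call was lost without humanized replicate 2 or 3 or wildtype replicate 1 (adjusted p = 0.136, 0.112 and 0.0929), and the LUC7 call without any humanized replicate, wildtype replicate 1 or triple mutant replicate 1 or 3 (0.0505 to 0.161). Other settings ended these calls too. YHC1 lost it after the offset for coding length and GC content (0.0522), in a fit of the 2 groups (0.0635) and in limma-trend (0.278), and LUC7 in the fit of 2 groups (0.0608) and in 1 of all 7 (0.163). The high-density YHC1 call was lost without humanized replicate 1 or 2 or wildtype replicate 1 or 2 (0.0505 to 0.0985), with the replicate number as a block (−0.36, 0.0644) and in limma-trend (0.143). That in the triple mutant was lost without its replicate 1 or 2 or wildtype replicate 1 (0.0610 to 0.0862), after the offset (−0.05, 0.526) and in limma-trend (0.420). After the offset YHC1 was called between the mutants (+0.18, 0.0476) and LUC7 at high density (+0.26, 0.0267). LUC7 was called there in limma-trend as well (+0.41, 0.0136).

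Nutritional marker genes separated the strains. URA3 had 660 ± 31.2 CPM (mean ± SD) in wildtype and 821 ± 14.5 in humanized cells at low density and no read in the triple mutant, at least a 26222-fold and a 32608-fold difference when 3 reads were allowed for the absent gene. LEU2 had 668 ± 178 CPM in the triple mutant and no read in wildtype or humanized cells, at least 19898-fold and 21617-fold. Undepleted degron cells also carried LEU2 (643 ± 153 CPM) and nearly no URA3 (1.06 ± 1.84 CPM), and LYS2 had no read in any of the 21 libraries (below 0.00418 CPM). These bounds cover counting error only.

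**Figure D1:**
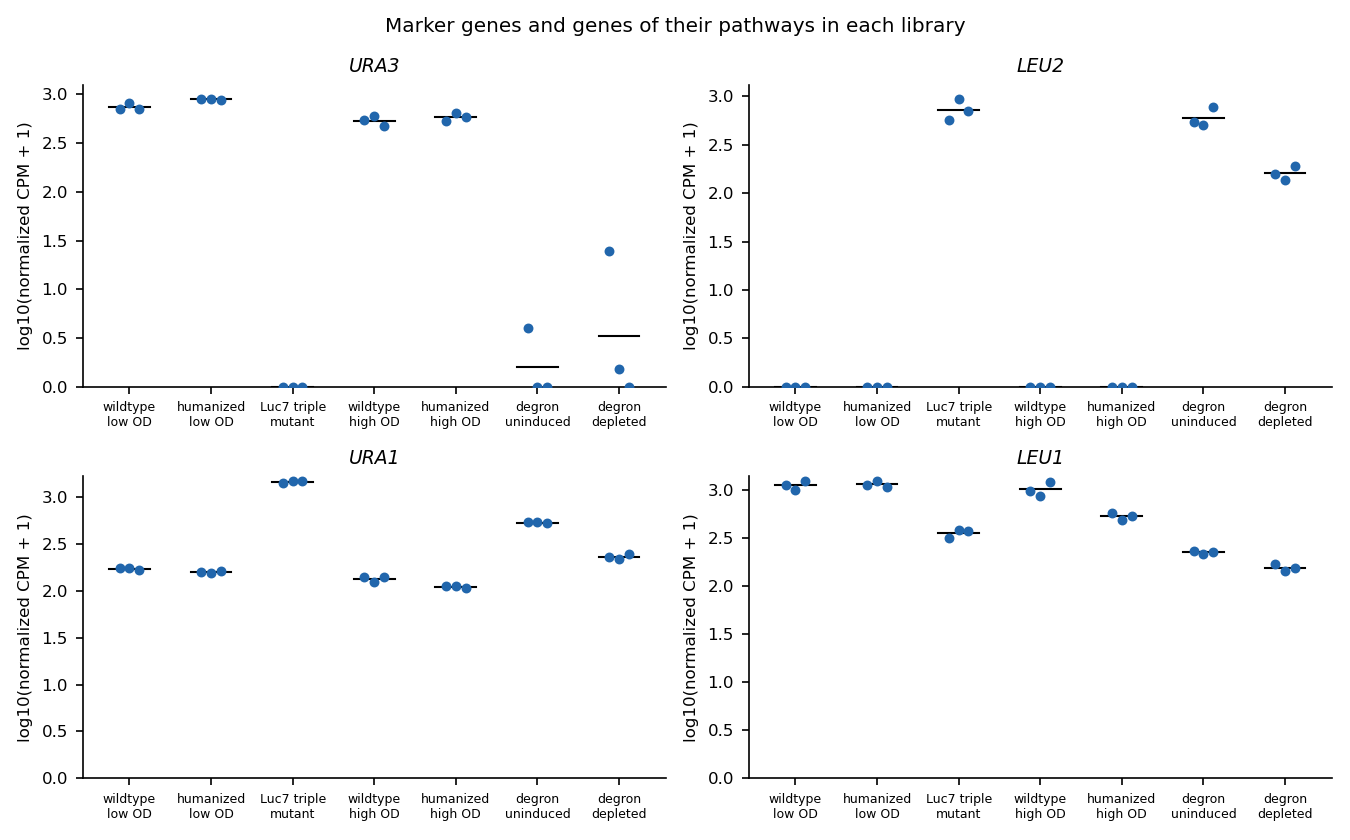
URA3, LEU2 and their pathway genes URA1 and LEU1 in each library, as log10 of normalized CPM plus 1. Bars are group means of 3 libraries.

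The first comparison asked which transcripts differed between humanized and wildtype cells at low density. RPS22B, a small-subunit ribosomal protein gene with an intron, was 2.34-fold lower in humanized cells (−1.23 ± 0.07, 3 libraries per group, 101 ± 5.21 against 236 ± 21.5 CPM, adjusted p = 1.18e-05, XII, 856442–857317, intron 856575–857057). RPS14B (−0.92 ± 0.07, X, 73787–74611, intron 73797–74204 with a GTACGT 5′ splice site) and NCB2, a subunit of the transcription repressor NC2 (−0.83 ± 0.06, IV, 1266366–1266898, intron 1266770–1266861), fell with adjusted p = 8.12e-05 each. BIG1, needed for cell wall glucan (−0.76 ± 0.09, VIII, intron 315772–315858), and the mitochondrial ribosomal protein gene MRPL44 (−0.73 ± 0.12, XIII, intron 721199–721345) fell as well. Without an annotated intron, RPL9B (−0.71 ± 0.06) and RPS25B (−0.70 ± 0.08) fell by less than RPS22B. Among higher genes, the glucose transporter gene HXT7 rose 2.01-fold (+1.01 ± 0.12, adjusted p = 0.00101, IV, 1154216–1155928) and the cell wall gene PIR3 rose (+0.75 ± 0.11). Most ribosomal protein genes, HXT7 and the subtelomeric Y′ genes such as YRF1-2 (+1.30 ± 0.19) and YJL225C (−0.74 ± 0.06) have near-identical copies, so which copy moved is uncertain. The same holds for YIL177W-A (−1.93 ± 0.16, the largest fall), which was not matched to the reference. The other genes among the 6 highest and 6 lowest were YFL066C, at a telomere (+1.51 ± 0.27), the hexokinase gene HXK1 (+0.68 ± 0.16), and YMR193C-A (+0.94 ± 0.10), YDR094W (−1.04 ± 0.24) and YIL047C-A (−0.97 ± 0.21), not matched to the reference.

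Intron-containing genes outside the ribosome fell as a group: 70 of 174 were lower and 6 higher (9 higher and 94 lower when adjusted over the list alone, median −0.26, adjusted p = 2.4e-24, 0.0259 with an estimated correlation). The 126 with the consensus GTATGT 5′ splice site had 63 lower and none higher (median −0.30, 82 lower and 1 higher over the list alone, adjusted p = 5.69e-39 and 0.0259 with an estimated correlation). The 48 with another site had 6 higher and 7 lower and were not called as a list (median −0.07, adjusted p = 0.753). The difference between the medians was −0.23 (permutation of genes, adjusted p = 0.00012 over 12 tests). Higher intron genes with other sites were MRX20 (GTAAGT, +0.66 ± 0.08, VI, intron 242010–242081), SRC1 (GTGAGT, +0.48 ± 0.07) and the meiotic gene SPO22 (GTATAT, +0.43 ± 0.07). Ribosomal protein genes with an intron fell (median −0.34, 1 higher and 70 lower of 89, 1 and 84 over the list alone, adjusted p = 5.24e-54, 0.303 with an estimated correlation), more than those without (median −0.20, 8 of 48 lower, 25 over the list alone, 4.45e-15 and 0.463; −0.11 without wildtype replicate 2, −0.12 after the offset and −0.03 in limma-trend). Wildtype replicate 2 carried the largest share of reads on ribosomal protein genes among the 3 controls (18.1%), and the group share was 16.7 ± 1.24% in wildtype and 14.4 ± 0.367% in humanized cells. The correlation of the change with intron length was 0.13 (Spearman, permutation p = 0.0936), and among genes of 10 CPM or more 0.17 (adjusted p = 0.0812) and, at high density, 0.22 (adjusted p = 0.0207). In limma on TPM, whose scale also shifted the median gene, the medians were −0.09 for non-ribosomal intron genes, −0.13 for those with GTATGT and −0.16 for ribosomal protein genes with an intron.

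**Figure D2:**
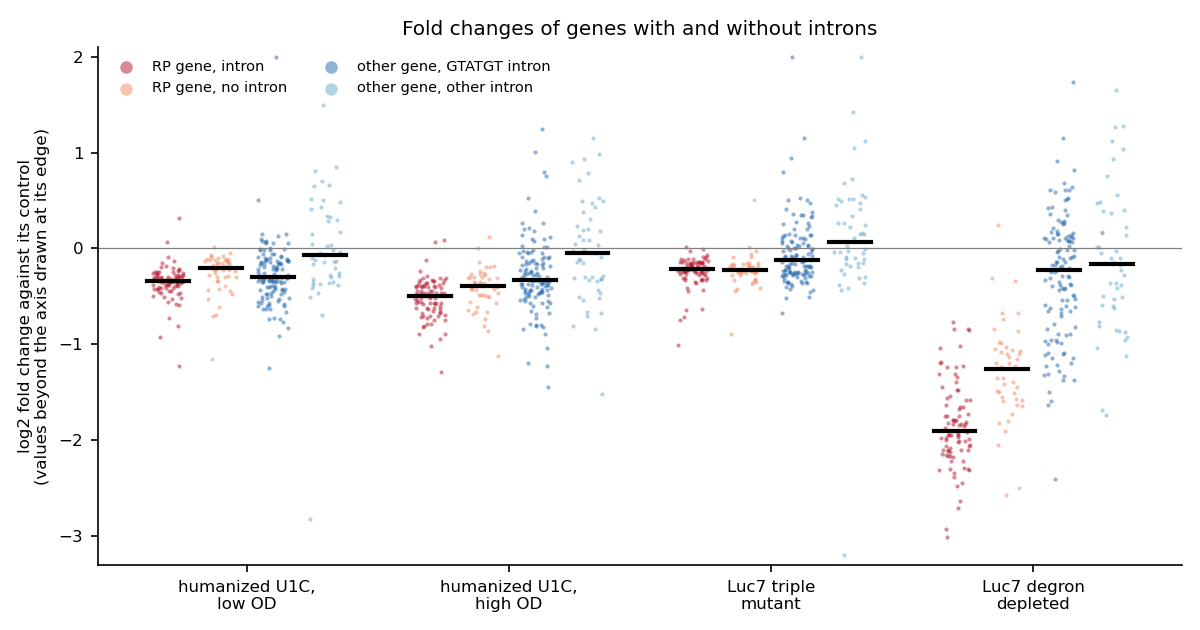
Log2 fold changes of ribosomal protein genes with and without an intron and of other intron genes by 5′ splice site in the 4 comparisons with a control. Black bars are medians and values beyond the axis are drawn at its edge.

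General stress genes rose at low density (median +0.21, 6 higher of 33, 10 over the list alone, adjusted p = 1.01e-05, 0.303 with an estimated correlation), among them TSL1 (+0.60 ± 0.07) and YGP1 (+0.49 ± 0.08). Hexose transporters rose (median +0.38, 4 of 16, 7 over the list alone, 1.01e-05 and 0.303). Their median was +0.25 without wildtype replicate 2 and +0.18 over genes of 10 CPM or more. Nuclear genes of the respiratory complexes rose slightly (median +0.08, 5 of 36, 8 over the list alone, adjusted p = 0.00326, 0.463 with an estimated correlation), with SDH2 of succinate dehydrogenase the largest (+0.38 ± 0.07), and their median was +0.18 after the offset. The mitochondrial ribosome list was called lower with only 2 of 65 genes called lower (median −0.07, 0.00326 and 0.695), and it lost the call after the offset (0.796) and without wildtype replicate 2 (0.0560). U1 snRNP (median −0.03, adjusted p = 0.719) and import genes (median −0.07, adjusted p = 0.0849) were not called. Mitochondrial-genome sequences had only 2–99 reads per library and were not tested as a list.

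In all, edgeR called 163 genes higher and 237 lower of 6107 tested, 10 and 4 of them by 2-fold or more; in 31.8% of genes the groups did not overlap, where 10% would by chance. DESeq2 called 431 and 431, a fit of only the 2 groups 63 and 141, and a fit of all 7 groups 95 and 107. The replicate number as a block gave 88 and 150, and limma on TPM 67 lower. Without humanized replicate 1, 2 or 3 the higher calls were 88, 31 and 27, without wildtype replicate 1, 2 or 3 they were 56, 93 and 889, and without triple mutant replicate 3, which shares the fit, 91. Lower calls were 75 without humanized replicate 2 or 3 and 110 and 681 without wildtype replicates 1 and 3. TSL1, YGP1 and YRF1-2 lost their calls in a fit of all 7 groups (adjusted p = 0.0829, 0.0616 and 0.0678), as did HXK1, YDR094W and YIL047C-A (0.0695, 0.0805 and 0.0609), which also lost them without humanized replicate 2 (0.124, 0.142 and 0.118) and without replicate 3. YFL066C lost its call without wildtype replicate 1 (0.0527) and SDH2 without humanized replicate 2 (0.0545).

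**Figure D3:**
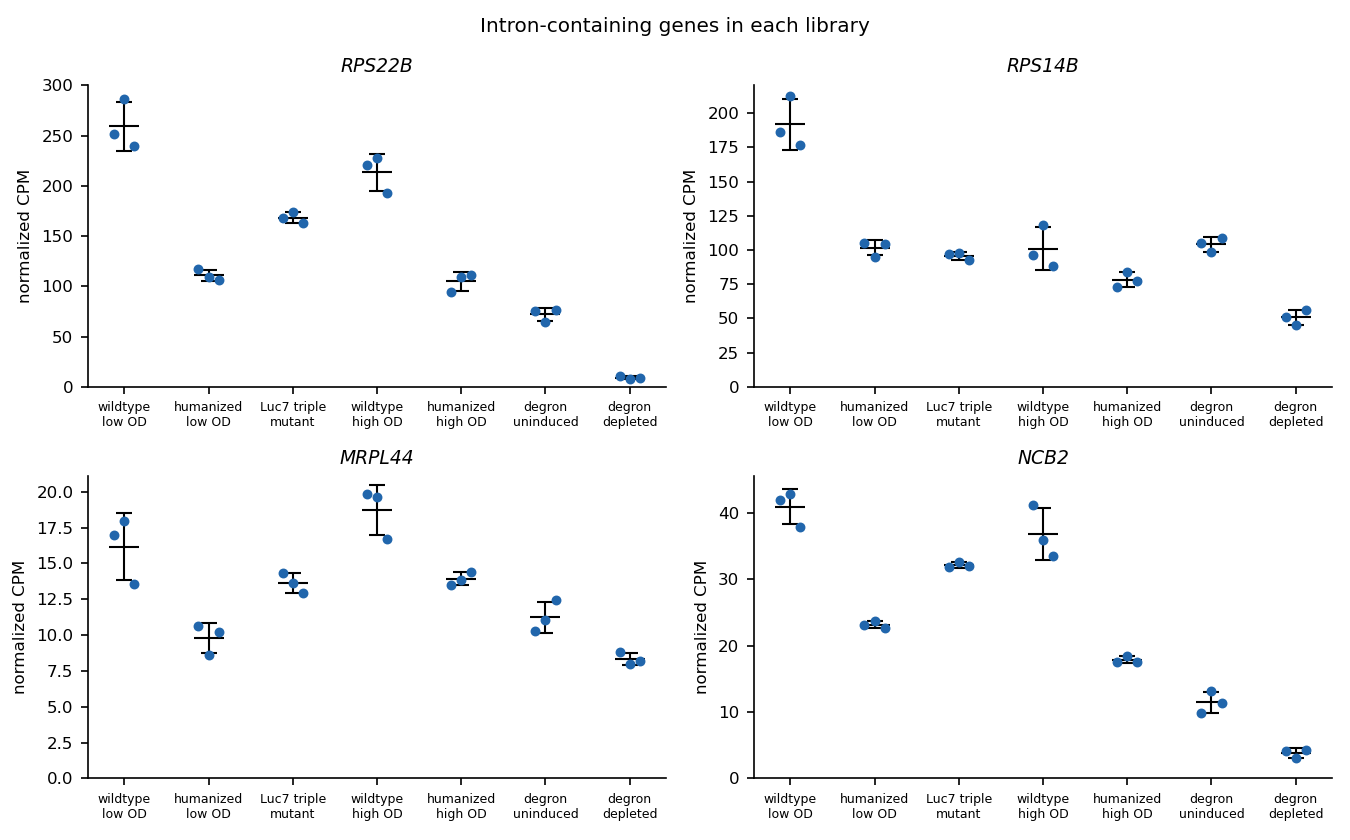
RPS22B, RPS14B, MRPL44 and NCB2 in each library. Values are normalized CPM, with group mean ± SD.

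The Luc7 triple mutant was set against the same 3 wildtype libraries to ask which transcripts differed between these strains. Besides Luc7 they differed in the markers URA3 and LEU2, and the medium of each group is not given in the sources used here. The differences below can therefore not be divided between Luc7, strain background and medium. HXT7 was 16.3-fold higher (+4.03 ± 0.13, 3 libraries per group, adjusted p = 4.32e-09) and HXT4 7.12-fold (+2.83 ± 0.16, VIII, 287081–288811). URA1 of pyrimidine synthesis (+3.08 ± 0.05, adjusted p = 7.93e-12, XI, 25215–26159), MDH2 of gluconeogenesis (+3.08 ± 0.06, XV, 81787–82920), the arginine gene ARG1 (+2.64 ± 0.07, XV, 219211–220473) and the glycogen synthase gene GSY1 (+2.10 ± 0.17) rose too. Lower genes were the mitochondrial carriers DIC1 (−1.69 ± 0.09, XII, 826977–827873) and OAC1 (−1.61 ± 0.10) and the leucine gene LEU1 (−1.67 ± 0.10, VII, 476313–478652, adjusted p = 6.7e-07). YRF1-3 (+2.88 ± 0.67, adjusted p = 0.0951 in DESeq2), YHR219W (−1.68 ± 0.22) and YFL068W (−1.49 ± 0.17), at telomeres, were also among the highest and lowest. Among intron genes, RPS14B (−1.01 ± 0.07), RPS9A (−0.74 ± 0.09), RPL18B (−0.71 ± 0.06) and the ribosome assembly gene NOG2 (−0.67 ± 0.05, XIV, intron 721771–722302) fell, whereas OM14, of the mitochondrial outer membrane, rose (+1.15 ± 0.07, II, intron 679943–680039).

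Ribosome biogenesis genes fell (median −0.31, 1 higher and 60 lower of 68, adjusted p = 1.94e-13, 0.282 with an estimated correlation), with DBP8 (−0.87 ± 0.06) and UTP23 (−0.62 ± 0.07) at the low end. General stress genes (median +0.63, 22 higher and 2 lower of 33, 1.26e-11 and 0.282) and hexose transporters (median +0.67, 13 of 16 higher, 1.03e-07 and 0.282) rose. Gcn4 targets of amino acid synthesis rose (median +0.19, 21 higher and 5 lower of 36, adjusted p = 6.96e-06, 0.282 with an estimated correlation) and so did glucose-repressed genes (median +0.20, 13 and 1 of 25, 1.02e-05 and 0.282). Proteasome genes fell (median −0.25, 27 of 34, 2.9e-05 and 0.437), as did ergosterol genes such as ERG2 (−0.52 ± 0.05, list median −0.23, 0.00132 and 0.282), iron regulon genes (median −0.27, 4 higher and 15 lower of 26, 0.00422 and 0.608) and targets of the mitochondrial retrograde response (median −0.42, 1 and 5 of 8, 0.0131 and 0.282).

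Non-ribosomal intron genes were not called in the triple mutant (33 higher and 64 lower of 174, median −0.09 and mean +0.03, adjusted p = 0.151). Those with GTATGT lay lower than those with other sites by 0.19 in the median (permutation of genes, adjusted p = 0.00606), and as a list they were lower (median −0.12, mean −0.00, 19 higher and 54 lower of 126, adjusted p = 0.0256, 0.608 with an estimated correlation). Over all 174 non-ribosomal intron genes the fold changes fell with baseline expression (Spearman −0.43, adjusted p = 0.00012). Ribosomal protein genes with and without an intron fell (medians −0.21 and −0.22, 59 of 89 and 31 of 48 lower, adjusted p = 4.71e-07 and 0.000109, 0.608 and 0.614 with an estimated correlation). Mitochondrial ribosome genes such as MRPS16 (−0.51 ± 0.09) fell (median −0.24, 39 of 65, 3.71e-05 and 0.593), and respiratory complex genes were not called (median +0.03, adjusted p = 0.380) although SDH1 (+0.94 ± 0.09) and SDH2 (+0.77 ± 0.07) rose. edgeR called 1729 higher and 1620 lower of 6107, 205 and 51 by 2-fold or more, and groups did not overlap in 61.7% (10% by chance). After an offset for coding length and GC content the ribosomal protein lists with and without introns (adjusted p = 0.290 and 0.167) and the mitochondrial ribosome list (0.157) were no longer called, the consensus-site list neither (0.618), and the non-ribosomal intron median was +0.01. Ribosomal protein genes with an intron then lay 0.02 above those without (permutation of genes, adjusted p = 0.0308), and limma on TPM called 772 genes lower. Glucose-repressed genes and Gcn4 targets had medians of +0.06 and +0.12 after the offset. Without wildtype replicate 2 the median of ribosomal protein genes without an intron was −0.14, and the consensus-site list was not called (adjusted p = 0.0641). The limma medians were −0.07 for ribosomal protein genes with an intron and −0.07 for those without, −0.09 for the mitochondrial ribosome, −0.12 for the proteasome and −0.17 for ribosome biogenesis. They were −0.11 for ergosterol, −0.12 for iron regulon and −0.27 for retrograde genes, +0.35 for Gcn4 targets and +0.31 for glucose-repressed genes. After the offset the respiratory complex list was called higher (median +0.20, adjusted p = 0.00692).

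Directly against humanized cells, the triple mutant had 1087 genes higher and 985 lower of 6107, 107 and 29 by 2-fold or more, with groups not overlapping in 55.8% (10% by chance); limma on TPM called 596 higher. URA1 (+3.20 ± 0.05), HXT7 (+3.02 ± 0.12) and MDH2 (+2.92 ± 0.06) were higher, LEU1 (−1.69 ± 0.10), OAC1 (−1.53 ± 0.10) and LUC7 (−0.47 ± 0.09, adjusted p = 0.00252) lower. Non-ribosomal intron genes lay higher in the triple mutant (median +0.19, 60 higher and 6 lower of 174, adjusted p = 0.000443, 0.258 with an estimated correlation).

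At high density the humanized strain was compared with wildtype to see what the first experiment held. ARG1 of arginine synthesis was 5.38-fold lower (−2.43 ± 0.27, adjusted p = 0.00118), and ARG4 fell too (−2.03 ± 0.18, VIII, 140011–141402). YOR338W, of unknown function, was 6.04-fold higher (+2.59 ± 0.16, XV, 956898–957989), and the chaperone gene HSP82, whose close copy HSC82 makes its value uncertain, 4.57-fold (+2.19 ± 0.20, XVI, 96496–98625). At low and high density HSP82 had 304 and 72.8 normalized CPM in wildtype and 324 and 333 in humanized cells. ARG1 had 45.1 and 416 in wildtype and 43.6 and 76.9 in humanized cells. For both genes the larger difference between densities was in wildtype. HSP12 (+2.13 ± 0.16), HSP26 (+1.96 ± 0.13) and the succinate dehydrogenase genes SDH1 (+1.39 ± 0.12) and SDH2 (+1.23 ± 0.10) rose. Among intron genes RPS22B (−1.02 ± 0.10) and NCB2 (−1.04 ± 0.09) again fell, with the RNA helicase gene DBP2 (−1.45 ± 0.11, XIV, intron 414912–415913), POP8 (−1.23 ± 0.16, II, intron 186353–186427) and ERV1, of mitochondrial import (−0.90 ± 0.08, VII, intron 543639–543721). The phosphatase genes PHO11 and PHO12, near-identical copies, were lower (−1.69 ± 0.21 and −1.93 ± 0.15). YGR035C (+2.38 ± 0.32), RRT5 (+2.31 ± 0.09) and BSC1 (+2.10 ± 0.41) were among the 6 highest, ARO5 (−2.10 ± 0.12) and the arginine gene ARG7 (−2.06 ± 0.17) among the 6 lowest.

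Gcn4 targets were lower in 34 of 36 (median −0.89, 36 over the list alone, adjusted p = 8.57e-30, 0.434 with an estimated correlation) and phosphate genes in 11 of 15 (median −0.66, 1.21e-10 and 0.225). General stress genes (median +0.86, 24 of 33, 1.39e-14 and 0.434), respiratory complex genes (median +0.53, 24 of 36, 26 over the list alone, 5.33e-12 and 0.434), chaperones (median +0.33, 12 of 19, 3.29e-07 and 0.434) and tricarboxylic acid cycle genes (median +0.47, 11 higher and 2 lower of 17, 9.84e-06 and 0.434) rose. Drug efflux genes such as YOR1 (+0.67 ± 0.07) rose (median +0.53, 9 and 1 of 14, 0.0011 and 0.340), a call lost in limma-trend (0.139). Without wildtype replicate 2 the chaperone median was +0.53. Non-ribosomal intron genes fell (median −0.29, 8 higher and 67 lower of 175, 10 and 73 over the list alone, adjusted p = 2.65e-07, 0.434 with an estimated correlation), and GTATGT genes lay 0.28 below the others (permutation of genes, adjusted p = 0.00012). Ribosomal protein genes with an intron (median −0.49, 70 of 89 lower, 7.22e-21 and 0.434) and without (median −0.40, 23 of 48, 2.92e-09 and 0.434) fell, with group shares of reads of 15.5 ± 1.36% in wildtype and 12.3 ± 0.647% in humanized cells. edgeR called 978 higher and 774 lower of 6119, 83 and 61 by 2-fold or more, with groups not overlapping in 46.0% (10% by chance). Calls were 468 and 368 without humanized replicate 1, 429 and 370 without humanized replicate 2, and 466 and 338 without wildtype replicate 1; limma on TPM called 1780 higher and 283 lower. Lower calls were 1475 after the offset, 1308 with all 7 groups in 1 fit and 507 with the replicate number as a block. The limma medians were −0.05 for non-ribosomal intron genes, −0.18 and −0.14 for ribosomal protein genes with and without an intron, −0.31 for phosphate genes and +0.53 for chaperones.

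**Figure D4:**
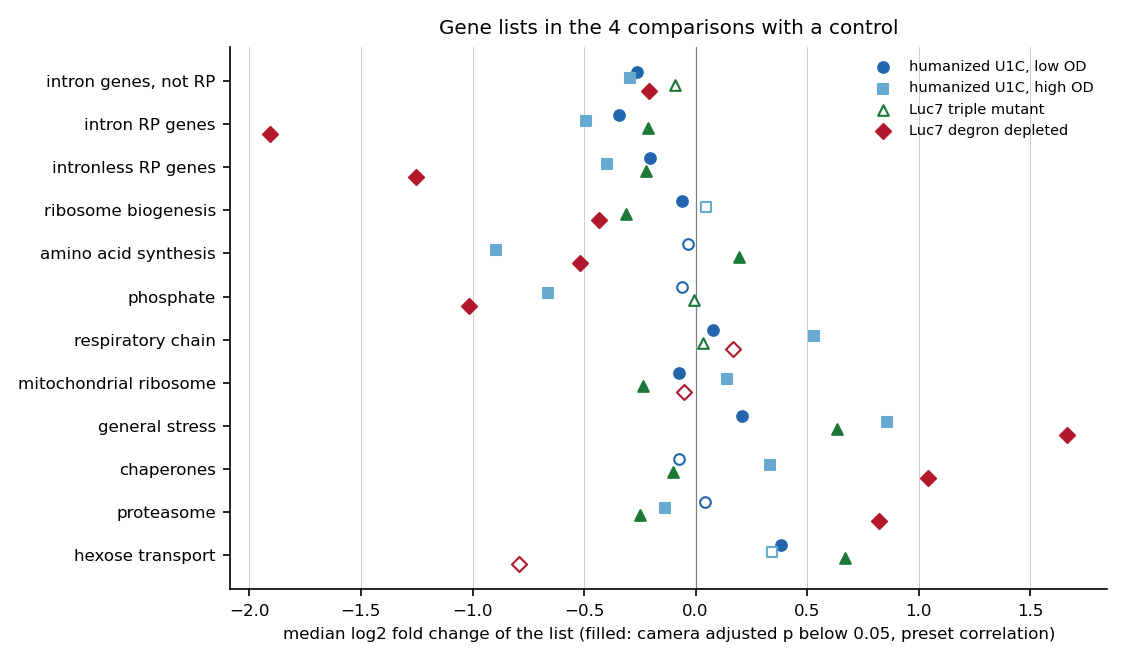
Median log2 fold change of 12 gene lists in the 4 comparisons with a control. Filled marks had an adjusted p below 0.05 with the preset correlation.

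Whether the effect of humanization differed between the densities was tested as an interaction, in which density and experiment are the same split. The effect was larger at high density for RRT5 (+3.08 ± 0.21, −0.76 at low and +2.31 at high density) and YOR338W (+2.68 ± 0.18), and lower for ARG1 (−2.37 ± 0.30, −0.05 and −2.43). Of 6150 genes, 605 had an interaction above 0 and 493 below, 68 and 64 by 2-fold or more. Gcn4 targets (median −0.82, 32 of 36 below 0, adjusted p = 5.05e-31, 0.428 with an estimated correlation) and respiratory complex genes (median +0.47, 16 of 36 above 0, 8.63e-09 and 0.590) differed, while non-ribosomal intron genes did not (median −0.00, mean +0.03, 7 above and 11 below 0 of 176, adjusted p = 0.633). Counts below 0 were 328 without wildtype low-density replicate 1, 269 in limma-trend and 797 without both wildtype libraries numbered 2, and the offset gave 938 above and 967 below.

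High against low density was also compared within each strain. In wildtype HXT7 (+3.72 ± 0.27), the cell wall sensor gene WSC4 (+3.63 ± 0.14, VIII, 48763–50580) and GCV1 of glycine breakdown (+3.45 ± 0.17) were higher and CMK2, a calmodulin kinase gene (−2.85 ± 0.09, XV, 294777–296120), lower at high density. In humanized cells HXT7 (+3.96 ± 0.27) and HSP26 (+3.86 ± 0.18) were higher and TDA6 (−4.18 ± 0.09, XVI, 841266–842669) and HSP30 (−3.98 ± 0.19) lower. Gcn4 targets rose in wildtype (median +0.49, 24 of 36, adjusted p = 1.22e-13, 0.464 with an estimated correlation), and respiratory complex genes rose in humanized cells (median +0.80, 35 of 36, 5.36e-11 and 0.390). edgeR called 1287 higher and 1393 lower of 6150 in wildtype and 1704 and 1644 in humanized cells, with groups not overlapping in 48.2% and 67.8% (10% by chance). limma on TPM called 2290 and 564 in wildtype and 2703 and 708 in humanized cells.

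Depletion of Luc7 in the degron strain asked what loss of the protein did within 1 strain. The small heat shock gene HSP26 was 49.6-fold higher (+5.63 ± 0.21, 3 libraries per group, adjusted p = 3.07e-08, II, 382030–382674), followed by the stress genes DDR2 (+4.99 ± 0.25, XV, 231570–231755), HSP12 (+4.22 ± 0.20) and HSP42 (+3.94 ± 0.11, IV, 806621–807748), with MNC1 (+4.24 ± 0.22) and the spore wall gene SPS100 (+3.79 ± 0.21) also among the 6 highest. HSP82 (+2.60 ± 0.07) and the proteasome gene PRE6 (+1.27 ± 0.06) rose. RPS22B was 8.03-fold lower (−3.01 ± 0.11, 9.98 ± 1.56 against 79.9 ± 7.10 CPM), and RPL31B (−2.93 ± 0.16, XII, intron 931350–931698), RPS10A (−2.17 ± 0.08) and ASC1, a ribosome-bound protein gene (−2.40 ± 0.15, XIII, intron 499879–500151), fell. HXT4 (−3.70 ± 0.18), the purine gene ADE17 (−3.44 ± 0.11, XIII, 507502–509280), PHO12 (−3.91 ± 0.13), PHO11 (−3.27 ± 0.12) and IZH4 (−3.01 ± 0.12) were the lowest besides. Other intron genes that fell were YOP1 (−1.63 ± 0.06, XVI, intron 623578–623710) and PFY1, encoding profilin (−1.37 ± 0.06), and LDS2, also of the spore wall, rose (+1.74 ± 0.13, XV, intron 242442–242504). YHC1 rose (+0.34 ± 0.08, adjusted p = 0.00258) and LUC7 was not called (+0.30 ± 0.18, adjusted p = 0.171), but was with the replicate number as a block (0.00308), in limma-trend (0.0334) and without undepleted replicate 3 (+0.55, 0.00752). The degron acts on the protein, so neither measures depletion.

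Ribosomal protein genes with an intron fell in all 89 cases (median −1.91, adjusted p = 2.27e-61, 0.221 with an estimated correlation), those without in 46 of 47 with 1 higher (median −1.25, 5.65e-23 and 0.221), and their share of reads was 12.8 ± 0.459% without and 4.86 ± 0.486% with depletion. General stress genes (median +1.67, 33 of 34 higher, 2.16e-23 and 0.221), proteasome genes (median +0.82, 33 of 34, 2.76e-15 and 0.221) and chaperones (median +1.04, 18 of 19, 3.36e-14 and 0.221) rose. Phosphate genes (median −1.02, 14 of 15 lower, 1.43e-11 and 0.201), Gcn4 targets (median −0.52, 26 of 36, 3.9e-07 and 0.221) and a-specific mating genes (median −1.73, 6 of 6, 5.04e-06 and 0.201), BAR1 (−1.99 ± 0.08) and STE6 (−1.47 ± 0.07) among them, fell. Non-ribosomal intron genes fell (median −0.21, 32 higher and 82 lower of 175, adjusted p = 0.0187, 0.436 with an estimated correlation), with no difference by 5′ splice site (−0.06, permutation of genes, adjusted p = 0.673). Respiratory complex genes were not called (median +0.17, 13 higher and 9 lower of 36, adjusted p = 0.789). edgeR called 2090 higher and 2111 lower of 6156, 390 and 411 by 2-fold or more, with groups not overlapping in 73.7% (10% by chance). limma on TPM gave 3379 and 1120, on a scale where the median gene was at +0.28. There the non-ribosomal intron median was +0.07, below the median gene, and the list stayed called (camera adjusted p = 0.00428). Gcn4 targets were at −0.25 on that scale. A strain without the degron given beta-estradiol and IAA was not analysed here, so the treatment and the depletion are not separable. The densities of the degron cultures are not given in the sources used here, so a difference in density is not separable either. Of the genes named above for density in wildtype, CMK2 and HXT7 moved on depletion as from high to low density (83.2 to 422 and 482 to 269 normalized CPM). WSC4 (45.6 to 45.4) and GCV1 (157 to 147) barely moved. The naming rule also gave YOR385W, SRL3 and DIA1, which like CMK2 were lower at high density in wildtype. They rose on depletion as CMK2 did (31.1 to 171, 9.14 to 57.9 and 36.2 to 243). It also gave YFR052C-A, higher at high density, which barely moved (17.6 to 15.4). The genes low at high density thus moved as a lower density would move them, and those high there mostly did not.

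Shared calls were counted to ask which responses were common. Humanized cells at low density and the triple mutant shared 134 higher genes (46.1 expected of independent lists) and 169 lower (62.9), with 13 in opposite directions. The correlation of fold changes was 0.54, where 20 simulations of unchanged groups with a common control gave 0.43 to 0.57 and no shared call. At most 2 genes were called in either comparison of a simulation, and the simulated controls lacked the real trends with coding length. Neither the simulations nor independent lists therefore show how many shared calls a common control would give. The low and high density comparisons of humanized cells shared 44 higher (26.2 expected) and 135 lower genes (30.2), RPS22B and NCB2 among the lower, with 32 opposite. With Luc7 depletion, which shares no library with it, humanized cells at low density shared 101 higher (55.5 expected) and 169 lower genes (81.8), RPS22B among them. The triple mutant and the depletion shared 779 higher (588 expected) and 800 lower genes (559), and 815 moved in opposite directions, fewer than the 1148 expected of independent lists. HXT4, PRE6 and URA1 were among these 815.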

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

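In this part the length and GC offset, the intervals, the difference between ribosomal protein genes and the tests of pathway genes were chosen after the results had been seen, while the interaction, the single libraries left out and the exchange of libraries between groups were planned, with the left-out libraries shown here picked afterwards. The fall of intron genes in humanized cells at low density was held against trends of fold change with coding length, 1 wildtype library apart from the others, and a fall of ribosomal protein genes as a class. After the offset for coding length and GC content the median of non-ribosomal intron genes was −0.198 (−0.229 to −0.169), and without wildtype low-density replicate 2 it was −0.216 (−0.249 to −0.170), both against the first 2 explanations. Ribosomal protein genes with an intron lay below those without by −0.122 (−0.164 to −0.060) after the offset, which argues against a class effect alone, though the interval reaches above the −0.1 that was predicted before this test was run, and the looser bound of −0.05 on the interval was set after it had been seen. It stays open whether the fall is lost spliced RNA, decay of unspliced RNA or neither, because only coding sequences were counted.

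The uracil and leucine genes shifted in the Luc7 triple mutant were held against its marker genes. Undepleted degron cells, which also had LEU2 reads and nearly no URA3, had URA1 at +1.64 (1.53 to 1.76) over wildtype at low density. Their median for Leu3 targets was −1.24, and both values met the prediction of the marker explanation. The uracil shift was smaller than in the triple mutant, where URA1 was +3.08. The median of 3 targets of the uracil regulator Ppr1 was +0.54 in undepleted cells and +1.75 in the triple mutant. Undepleted cells also differed from wildtype in LUC7 (96.8 against 42.5 normalized CPM) and RPS22B (72.1 against 259), so more than the markers differed. The density of the degron cultures is not given in the sources used here. Depletion of Luc7 moved URA1 by −1.22 (−1.34 to −1.10), where the prediction for the Luc7 defect as the cause was a rise. This cannot decide the cause, since the depletion came with beta-estradiol and IAA. It also moved HXT4 and PRE6 in the direction opposite to the triple mutant. Leu3 targets fell on depletion too (median −0.54, against −0.39 in the triple mutant), so for the leucine genes the Luc7 defect is not excluded either. Density, media and other differences between the strains stay open.

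More genes were called between the strains at high than at low density, in fits of different form. Fits of the same form kept the difference, which argues against the form as its source. They gave 202 calls at low and 2704 at high density with all 7 groups, and 204 and 1752 with only the 2 groups. However, leaving out wildtype low-density replicate 3 raised the low-density calls from 400 to 1570. Single libraries left out at high density gave 799 to 1986, so the difference in counts is not settled. The 1752 calls at high density cannot be divided between strain and the different densities at harvest, since both are the same split, and that prediction was written after the result. After the offset 1905 interaction genes were called, meeting the prediction against length and GC trends. The calls between the strains were then 493 at low and 2714 at high density, which also argues against these trends as the source of the difference. Without wildtype high-density replicate 2 there were 1540 interaction genes. The number of interaction calls follows the high-density difference, as the exchange of libraries below shows, so by itself it tests neither explanation. Without that library 1986 genes were called at high density, 1594 of the 1752 among them, so most of those calls do not rest on it. Whether wildtype cells grown to the higher density would look alike stays open.

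Exchanging libraries between groups gave 1 of 10 splits with as many calls, the real one, in each comparison of 3 against 3 libraries, too few for a share under 0.05. The real splits had 400 calls in humanized cells at low density, 3349 in the triple mutant, 2072 between the mutants, 1752 at high density, 4201 in the depletion, 2680 for density in wildtype and 3348 in humanized cells, and the highest other split had 0. For the interaction 2 of 100 drawn splits, the real one included, had as many calls as the real 1098, the highest other with 1273. The 7 other splits that kept the true high-density groups had 756 to 1273 calls and the rest at most 310, so the number of calls follows the high-density difference and does not by itself measure the interaction.

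The interaction was called above 0 in 605 genes and below 0 in 493. As the exchange of libraries showed, these counts do not by themselves measure how the effect of humanization differed between densities. In the high-density experiment the 2 strains were also harvested at different densities. List medians of the interaction were −0.82 for Gcn4 targets, −0.63 for phosphate genes, +0.75 for general stress genes, +0.48 for chaperones, +0.47 for respiratory complex genes, +0.42 for the tricarboxylic acid cycle, +0.26 for the mitochondrial ribosome, −0.17 for the proteasome and −0.16 each for all ribosomal protein genes and those with and without an intron. With an estimated correlation none of these 11 lists was called (adjusted p = 0.0845 to 0.931). The proteasome list and those of all ribosomal protein genes and of those with and without an intron lost their calls without wildtype high-density replicate 2 (adjusted p = 0.182, 0.182, 0.229 and 0.261) and without wildtype low-density replicate 3 (0.0566, 0.0566, 0.0749 and 0.199), the last also without replicate 1 of either humanized group or of wildtype at low density (0.0526 to 0.0851). Single genes were RRT5 (+3.08), YOR338W (+2.68), YGR035C (+2.60), HSP82 (+2.11), ARG1 (−2.37), ARG4 (−2.01) and RGI1 (−2.01).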

How the results depend on the processing

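The length and GC offset and the fit without both wildtype libraries numbered 2 were chosen after the results had been seen; the other settings were not. Of 150 gene counts with 1 library left out 132 kept their size, 16 were weaker and 2 stronger, and under other settings 128, 15 and 11 of 154. Of 699 list medians with 1 library left out 661 stayed the same, 32 were weaker and 6 reversed, and under other settings 780, 100 and 18 of 899, with 1 stronger. Of 1611 values of named genes 1524 stayed, 84 were weaker, 1 stronger and 2 reversed with 1 library left out, and 1793, 58, 6 and 3 of 1860 otherwise. The cause was not tested.

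DESeq2 called 431 higher and 431 lower in humanized cells at low density. limma-trend on TPM, on whose scale the median gene moved by +0.00443 to +0.276, called 67 lower there, 772 lower in the triple mutant, 596 higher between the mutants, 1780 higher and 283 lower at high density, 3379 and 1120 in the depletion, 269 below 0 in the interaction, 2290 and 564 for density in wildtype and 2703 and 708 in humanized cells. Its list medians reversed in humanized cells at low density for other splice sites (+0.0781), the mitochondrial ribosome (+0.0828), the iron regulon (+0.0176) and ribosome biogenesis (+0.0915); in the triple mutant for intron genes (+0.0426), GTATGT genes (+0.00883), chaperones (+0.0289) and LUC7 (+0.0417); at high density for other sites (+0.16) and the proteasome (+0.0441). In the depletion intron genes (+0.0709), GTATGT genes (+0.0505), other sites (+0.11) and the mitochondrial ribosome (+0.23) reversed, in the interaction intron genes (+0.0274) and other sites (+0.0421), and for density YHC1 in wildtype (+0.18) and humanized cells (+0.13).

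All 7 groups in 1 fit gave 95 higher and 107 lower in humanized cells at low density and 1308 lower at high density; only the 2 groups gave 63 and 141. The replicate number as a block gave 88 and 150, and 507 lower at high density. The length and GC offset gave 1475 lower at high density, 938 and 967 in the interaction, −0.0353 for ribosomal protein genes with an intron in the triple mutant, and reversed intron genes there (+0.0105), other sites at high density (+0.0066) and respiratory complex genes in the depletion (−0.22). Without both wildtype libraries numbered 2 the interaction had 797 below 0. With an estimated correlation the calls of ribosomal protein genes with an intron were lost at unchanged medians (−0.34, −0.21, −0.49 and −1.91 in the 4 comparisons with a control; adjusted p = 0.303, 0.608, 0.434 and 0.221), and those of other intron genes at high density (−0.29, 0.434) and in the depletion (−0.21, 0.436).

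With 1 library left out, higher and lower calls ran from 27 to 889 and 75 to 681 in humanized cells at low density, 1473 to 1797 and 1352 to 1770 in the triple mutant, 747 to 1370 and 682 to 1353 between the mutants, 429 to 1135 and 338 to 851 at high density, 1906 to 2138 and 1917 to 2067 in the depletion, 420 to 831 and 328 to 709 in the interaction, 1013 to 1484 and 1044 to 1521 for density in wildtype and 1444 to 1833 and 1413 to 1773 in humanized cells. Intron gene medians ran from −0.29 to −0.22, −0.11 to −0.07, −0.33 to −0.24 and −0.22 to −0.18 in the 4 comparisons with a control, and those of ribosomal protein genes with an intron from −0.38 to −0.26, −0.26 to −0.15, −0.55 to −0.43 and −1.97 to −1.80. In the interaction intron genes ran from −0.0569 to +0.0111, reversed without humanized low-density replicate 1 or 3, wildtype high-density replicate 2 or wildtype low-density replicate 3. Other sites ran from −0.115 to +0.0128 at high density and reached +0.0158 in the interaction without wildtype high-density replicate 3, and YHC1 ran from −0.0800 to +0.0238 for density in wildtype.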

Other observations

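The medians by single splice site and the comparison of directions between the Luc7 strains were looked at after the results had been seen and were not tested. In humanized cells at low density the 126 genes with GTATGT had a median of −0.30 (63 lower, none higher), and the 6 with GTATGC, which keeps the T at position 4 of the intron, −0.33 (3 lower). The 12 with GTAAGT had a median of −0.13 (1 higher, 2 lower) and the 10 with GTACGT −0.03 (1 higher, 2 lower). At high density the medians were −0.33, −0.33, −0.13 and +0.11 in the same order. The 6 with GCATGT, which also has T at position 4, had medians of +0.12 and +0.39 with none lower, so that base alone does not separate the sites. The groups other than GTATGT are small, and which base matters stays open.

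The triple mutant and the depletion of Luc7 moved general stress genes (medians +0.63 and +1.67), ribosomal protein genes (−0.22 and −1.74) and ribosome biogenesis genes (−0.31 and −0.43) the same way in the median. After the offset for coding length and GC content, however, ribosomal protein genes were at −0.04 in the triple mutant and not called (adjusted p = 0.157). Among stress genes HSP26 and HSP12 were lower in it (−1.36 and −1.75) and higher after depletion (+5.63 and +4.22). Calls in opposite directions were fewer than independent lists would give (815 against 1148). A few pathways differed in direction. Proteasome genes had a median of −0.25 in the triple mutant and +0.82 after depletion, and PRE6 was −0.52 and +1.27. HXT4 was +2.83 in the mutant and −3.70 after depletion, and Gcn4 targets were +0.19 and −0.52. With an estimated correlation none of these lists was called (adjusted p = 0.221 to 0.679). Whether the beta-estradiol and IAA treatment added its own response was not tested.

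Depleted degron cells had lower a-specific and haploid genes (medians −1.73 and −0.86, adjusted p = 0.201 and 0.221 with an estimated correlation), with BAR1 at −1.99, STE6 at −1.47 and FAR1 at −1.55, and STE2 kept 327 ± 11.6 CPM against 784 ± 52.4. In the high-density experiment both strains had more of the a-specific genes than at low density (medians +1.21 in wildtype and +1.75 in humanized cells, adjusted p = 0.166 and 0.159 with an estimated correlation). STE2 had 932 ± 70.3 CPM in wildtype at high and 442 ± 45.4 at low density, so its fall on depletion went the same way as from high to low density. Between densities in humanized cells, the haploid list alone kept its call with an estimated correlation. URA3 reads in the degron strain were uneven: 771 in depleted replicate 1 (27.1 CPM), 20 in replicate 2 and 101 in undepleted replicate 1 (3.19 CPM), the rest with none. Whether these are reads of other libraries was not tested.

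Fold change rose with coding length in humanized cells at low density (Spearman 0.53) and in the triple mutant (0.48), less at high density (0.20). Deviations of single libraries from their group also followed coding length. Wildtype replicates 2 and 3 lay apart in opposite directions at low density (−0.64 and +0.60) and at high density (−0.64 and +0.74). Humanized replicate 1 was at −0.56 at low and +0.51 at high density. Part of the shared direction of short transcripts at low density, such as those of ribosomal proteins, might come from the 3 wildtype controls there. The intron gene median without wildtype low-density replicate 2 was −0.216. Fold change rose with coding length between the triple mutant and humanized cells too (0.32). That comparison sets no wildtype library against another group, so the trend is not a matter of these controls alone.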
